A study of Mus musculus with 14 samples.

How the data were processed

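The series holds 14 mRNA libraries from C57BL/6 mice, 21 weeks old and fed a high-fat diet for 8 weeks: heart of 4 WT and 4 Fhl2 KO samples (numbers 1 to 4) and gWAT of 3 WT and 3 Fhl2 KO samples (numbers 1, 3 and 4). Tissue was flash frozen, RNA was extracted with Trizol and libraries were made with the Kapa mRNA HyperPrep kit. The deposited table holds raw read counts per Ensembl gene, which are whole numbers with no normalization, 1 column per library. The submitters' processing notes name FastQC, Picard, Trimmomatic 0.32, HISAT2 2.1.0, HTSeq 0.11.0, limma and the mouse build mm10 (GRCm38), with no role or order. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Values of genes that overlap another gene, antisense genes and members of near-identical families are therefore uncertain.

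The table has 33459 gene IDs, of which 33406 carry a symbol. The 53 others hold 0.0132% of all reads and were tested without being named. In all libraries 2812 IDs are at 0, and 16 symbols stand on more than 1 ID. There are 0 columns without a sample. Totals are 10835100 to 13272400 counts per heart library and 15105000 to 16040200 per gWAT library. Gene coordinates were taken from GENCODE release M21 on GRCm38. Labels were checked with marker genes: Myh6 (heart muscle myosin) and Adipoq (adiponectin) were high in heart and gWAT libraries respectively. The sex of the mice is not labelled, and Y-linked Ddx3y was at 80.3 to 157 CPM and Xist at no more than 0.315 CPM in all 14 libraries. Of the 18 pairs of libraries within a group, none was a duplicate (chi-square per degree of freedom of 3.74 or more), and pairs across groups were not compared in this way.

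Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. For each tissue on its own, genes were filtered with filterByExpr by group, scaled with TMM and tested with the edgeR quasi-likelihood F test for KO against WT, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 0.149 in heart and 0.168 in gWAT. The standard error of a fold change was its size divided by the square root of F. CPM in the text use TMM-scaled library sizes except where stated. The levels of Ddx3y and Xist and the mean log2 levels of lists use library totals without scaling factors. The difference of the genotype effect between tissues was an interaction contrast in 1 fit of all 14 libraries. Calls within 20 Mb of Fhl2 were tested with Fisher's exact test, two-sided. The same test was planned for shared calls, but with the removed gene as the 1 heart call it says nothing about sharing, so its p is not given.

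For the gene sets, 55 lists of pathways and cell types were written down, and those with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry, which asks whether a list's genes move one way on balance without comparison to other genes, were the alternatives. Of the called lists, 0 in either tissue held with an estimated correlation. Lists are described with their counts over all genes tested and adjusted over the list alone.

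The named genes are, per tissue, Fhl2, the 10 higher and 10 lower genes with the largest absolute log2 fold change among those past the threshold, with mean log2 CPM above 1 and groups that do not overlap. From these 10 higher and 10 lower genes, symbols of predicted genes (Gm and a digit, or ending in Rik), pseudogenes and antigen receptor segments were left out, which was not done in the other parts of the rule. Up to 4 members with the smallest p of each described list, up to 10 genes called in both tissues and the 10 with the smallest p in the interaction were added. Fewer than 5 genes passed in heart, so the 5 with the smallest p in each direction are named as values that did not pass. Genes that this rule takes but the text does not name are not reported here. Other genes named as members of a small count were chosen after their values were seen. The groups, tests, lists, naming rule and a list of alternatives were fixed before the data were examined.

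The alternatives were edgeR's RLE scaling with DESeq2 size factors, no filter beyond 1 count, a filter at a mean of 10 counts and log2 CPM above 1, DESeq2, limma-voom, a robust dispersion fit, 1 fit for all libraries, the replicate number as a block, adjusted p thresholds of 0.1 and 0.01, windows of 10 and 40 Mb, and leaving out each library in turn. After the data were seen, a covariate for heart numbers 1 and 2 against 3 and 4, fits within these number sets, the mean log2 atrial level as a covariate, library totals without scaling factors, and RLE scaling for the gene lists were added.

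Equal numbers were checked for pairing by correlating each library's deviation from its group mean between WT and KO, with pairing read where every correlation was over 0.1. In heart the correlations of equal numbers were 0.25, 0.36, 0.33 and 0.26, which met this rule. Unequal numbers within the set of 1 and 2 gave 0.45 (WT 1 with KO 2) and 0.17 (WT 2 with KO 1). Within the set of 3 and 4 they gave 0.32 (WT 3 with KO 4) and 0.26 (WT 4 with KO 3). The values therefore show the sets of numbers and do not show pairing within them. In gWAT the correlations of equal numbers were −0.12, −0.21 and 0.01, which did not meet this rule. Pairing was not seen there, but with 3 libraries per group it is not excluded. Every split of a tissue's libraries into groups of the same sizes, and 40 regroupings for the interaction drawn with seed 20, were run through the same tests.

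The tests were tried on simulated counts with the spread of these data, in which 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The shares called depend on this number of changed genes. With fewer changed genes the adjustment asks for a smaller p, and smaller shares would be called. In heart 43.3%, 79.1% and 98.5% of 1.5-fold, 2-fold and 4-fold changes were called among 14159 genes, with 10 unchanged genes called. In gWAT the shares were 11.9%, 58.2% and 86.4% among 15200 genes with 13 unchanged genes called, and for the interaction 7.46%, 38.8% and 74.2% among 16014 genes with 2. With no change simulated, 0 genes were called in heart and 1 in gWAT.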

Results

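Heart and gonadal white adipose tissue (gWAT) were compared between wild-type (WT) mice and mice lacking Fhl2, a LIM-domain protein that binds transcription factors and sarcomere proteins. All mice were C57BL/6, 21 weeks old, and had eaten a high-fat diet for 8 weeks. mRNA was sequenced from 4 WT and 4 knockout (KO) hearts and from 3 WT and 3 KO gWAT samples. Values are deposited read counts, tested per gene with edgeR within each tissue. A fold change is log2 of KO over WT, given ± its standard error (SE). A level in CPM, read counts scaled to the size of the library, is given as mean ± SD, with n = 4 per group in heart and n = 3 in gWAT. The labels do not say that each library came from a separate animal, so the p-values measure the spread between samples.

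Fhl2 itself fell in both tissues of the KO mice. In heart, where WT samples held 1197 ± 176 CPM, KO samples held 34 ± 3.89 CPM, a log2 fold change of −5.14 ± 0.14 (adjusted p = 1.99e-08). In gWAT the gene was weakly transcribed, with 5.43 ± 0.980 CPM in WT and 0.390 ± 0.115 CPM in KO samples, a log2 fold change of −3.78 ± 0.31 (adjusted p = 0.0101). These gWAT levels rest on 257 reads over the WT libraries and 18 over the KO libraries. Every KO library lay below every WT library of its tissue. Fhl2 (ENSMUSG00000008136) lies on the minus strand of chromosome 1 from 43123074 to 43196984 in the GRCm38 build, and the labels do not say which part was removed, so reads from a remaining part would still be counted. The gWAT Fhl2 log2 fold change lost its call when single libraries were left out: adjusted p = 0.092 without WT replicate 4, and 0.060, 0.073 and 0.093 without KO replicates 1, 3 and 4. The loss of Fhl2 was not shown to differ between the tissues (difference 1.37 on the log2 scale, interaction adjusted p = 0.0875).

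**Figure D1:**
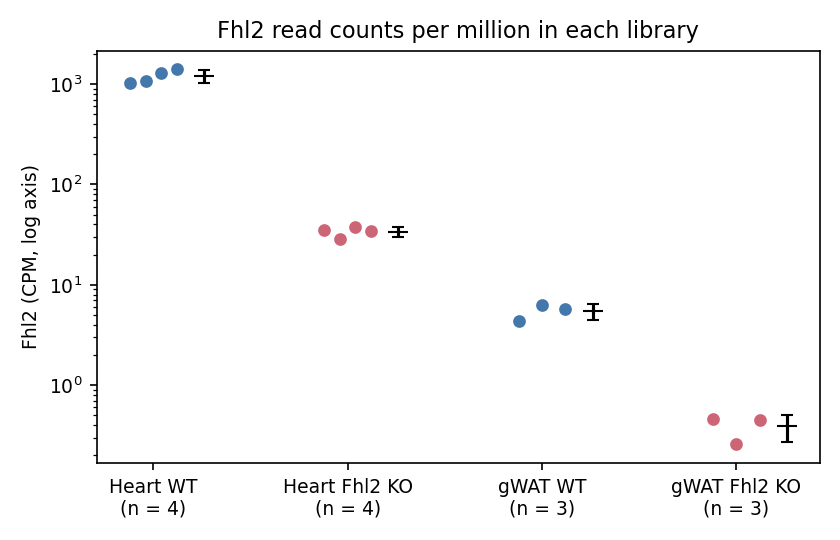
Fhl2 level in each library (points) in CPM on a log axis, by tissue and genotype, with the mean and SD of each group in black (n = 4 for heart, n = 3 for gWAT). KO hearts held 34 ± 3.89 CPM against 1197 ± 176 CPM in WT hearts, and KO gWAT 0.390 ± 0.115 CPM against 5.43 ± 0.980 CPM.

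Genes of lipid-laden macrophages, of cell division and of sterol synthesis fell in KO gWAT, and several adipocyte genes rose. Among the genes with the largest falls was Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, from 53.5 ± 28.7 to 3.95 ± 0.863 CPM (log2 fold change −3.76 ± 0.47, adjusted p = 0.0185). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, fell from 1580 ± 1128 to 159 ± 22.4 CPM (−3.31 ± 0.60, adjusted p = 0.0285). Hmga2, a chromatin protein of proliferating cells, had the largest fold change of the lower genes named here (−4.82 ± 0.82), but on 215 reads in WT and 7 in KO libraries. The other lower genes with the largest changes were Nptx1, a secreted pentraxin (−4.55 ± 0.74, 300 against 12 reads), Fat3, an atypical cadherin (−4.23 ± 0.75), Creg2 (−4.08 ± 0.81, 199 against 11 reads), Pcp4l1 (−3.60 ± 0.66), Rptoros (−3.30 ± 0.48) and Ptchd1 (−3.26 ± 0.60). Rptoros runs antisense to Rptor, and its value is uncertain because the strand setting of the counting is not given. Creg2 lies on chromosome 1 from 39618406 to 39651474, within 20 Mb of Fhl2, where DNA of another strain can remain around a targeted gene. Its fall cannot be told apart from an effect of such DNA.

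Among the genes that rose in KO gWAT, Cfd (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), the adipocyte-secreted protease adipsin, went from 328 ± 156 to 1539 ± 217 CPM (2.23 ± 0.31, adjusted p = 0.0216). Fam13a rose from 53.5 ± 22 to 213 ± 60.04 CPM (1.99 ± 0.30, adjusted p = 0.0236). Mycl, a transcription factor of the Myc family, rose from 4.70 ± 2.02 to 22.2 ± 3.56 CPM (2.25 ± 0.28, adjusted p = 0.0185). Mrgprg, an orphan receptor (3.12 ± 0.69), Acsm3, a mitochondrial medium-chain acyl-CoA synthetase (2.39 ± 0.45), Rnase2a, a ribonuclease (2.23 ± 0.46), and Orm3, an acute-phase glycoprotein (1.84 ± 0.23), also rose. So did Cadps, which acts in vesicle release (1.80 ± 0.34), Disp2 (1.76 ± 0.26) and Prtn3, a neutrophil serine protease (1.74 ± 0.26). Rnase2a and Orm3 belong to families of near-identical genes, and counting can move reads between their members.

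In all, edgeR called 834 of 15200 tested genes in gWAT at an adjusted p under 0.05, 305 higher and 529 lower in KO. Of these, 117 were at least 2-fold higher and 352 at least 2-fold lower. Every gene named here as having risen or fallen in gWAT was higher, or lower, in all 3 KO libraries than in all 3 WT libraries. The naming rule required this of the genes with the largest changes, so it adds no support. Groups did not overlap for 4227 tested genes (27.8%), where chance gives 10% on average. Genes move together, so this share is not a test. The count changed strongly when 1 library was left out: it was 2908 without WT replicate 1 and 132 without WT replicate 3. It was 0 without WT replicate 4 or KO replicate 1, 3 or 4. There edgeR gave 2374, 3191, 2736 and 2787 genes at an unadjusted p under 0.05. Such fits hold fewer libraries, so a count of 0 does not show that 1 library carried the calls. All 834 genes kept their direction and an unadjusted p under 0.05 in each of the 6 fits without 1 library. These genes were chosen by their p in all the libraries, most of which each fit reuses, so this agreement is not independent support. DESeq2 called 1769 genes, limma-voom 477, edgeR without a filter 1600 and edgeR on all 14 libraries 1725.

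**Figure D2:**
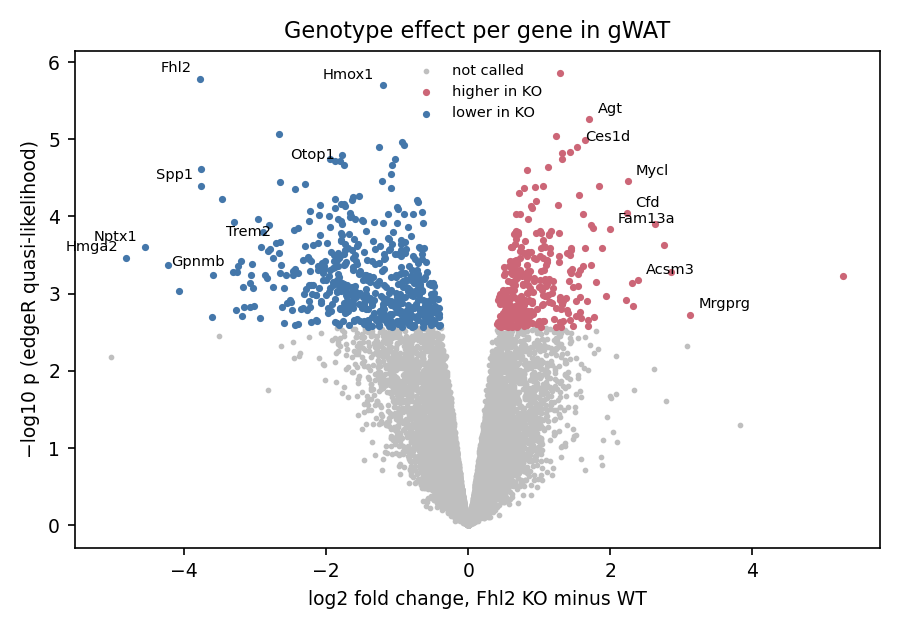
Each tested gene in gWAT (3 WT and 3 KO libraries), with the log2 fold change of KO over WT on the horizontal axis and −log10 of the edgeR p-value on the vertical axis. The 305 called genes that were higher in KO are red, the 529 that were lower are blue and the others grey.

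Genes of lipid-associated and inflammatory macrophages, the cells that take up lipid in obese fat, fell together in KO gWAT. Of the 13 tested, 11 fell and 0 rose over all genes tested, and 13 fell adjusted over the list alone, with a median log2 fold change of −2.15. Trem2, a lipid-sensing receptor, fell from 135 ± 75.4 to 21.4 ± 3.49 CPM (−2.66 ± 0.42, adjusted p = 0.0253), and Atp6v0d2, a subunit of the lysosomal proton pump, from 235 ± 129 CPM by 2.96 ± 0.43 on the log2 scale. Fabp5, a fatty acid-binding protein, fell less (−0.90 ± 0.13). The broader macrophage list moved less, with a median of −0.62: of its 17 genes Fcgr1, Cd68, Ctss and Adgre1 fell and Lyve1 rose over all genes tested, against 10 lower and 3 higher adjusted over the list alone. The 10 became 5 without WT replicate 3 or 4 or KO replicate 1, 3 or 4. Cd68, a lysosomal glycoprotein, went from 403 ± 217 to 101 ± 6.17 CPM (−2.00 ± 0.38), Fcgr1, an IgG receptor, changed by −1.96 ± 0.28 and Ctss, a cathepsin, by −1.44 ± 0.30. Lyve1, a receptor of tissue-resident macrophages and lymphatic endothelium, rose from 45.5 to 77.4 CPM (0.77 ± 0.17, adjusted p = 0.045). By camera the adjusted p was 1.37e-18 for the lipid-associated list, with adjusted p = 0.36 with an estimated correlation, the highest of its alternatives. For the broader list it was 0.00103, with adjusted p = 0.48 with an estimated correlation, again the highest.

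Cell cycle genes also fell in KO gWAT. All 20 tested genes fell, over all genes tested and adjusted over the list alone, with a median of −1.66. Ccna2, cyclin A2, went from 18.3 ± 3.66 to 5.33 ± 0.931 CPM (−1.78 ± 0.20, adjusted p = 0.0154) and Top2a, the DNA topoisomerase of dividing cells, from 47.7 ± 13 to 15.5 ± 2.34 CPM (−1.62 ± 0.21). Tpx2, a spindle protein, changed by −1.88 ± 0.22 and Cdk1, the mitotic kinase, by −1.81 ± 0.21. The adjusted p was 1.78e-36, with adjusted p = 0.36 with an estimated correlation, the highest of its alternatives. WT replicate 1 stood between the other WT samples and the KO samples: its mean log2 level of the lipid-associated macrophage list was 6.70, against 8.56 and 8.18 in WT replicates 3 and 4 and 5.78 to 5.96 in KO.

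**Figure D3:**
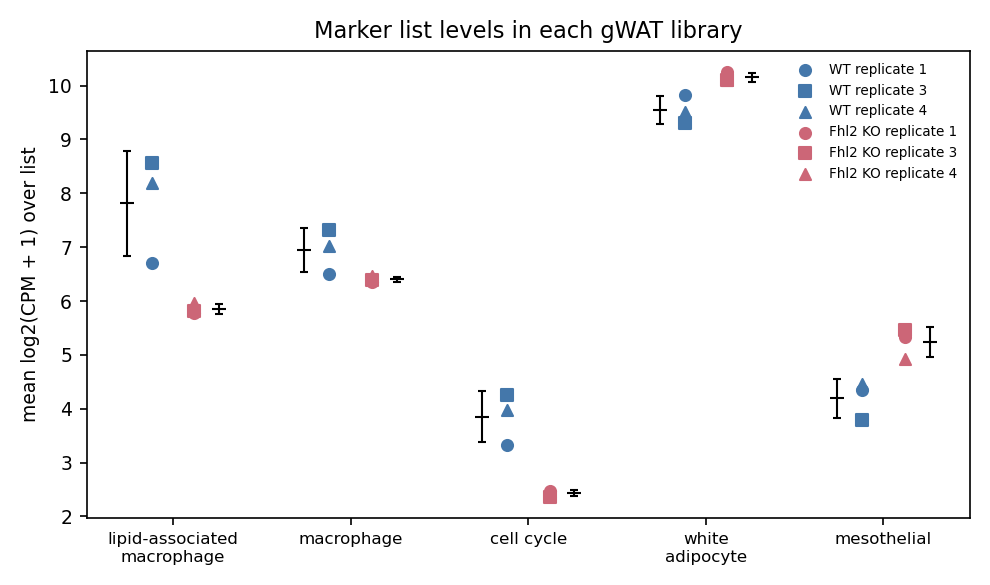
Mean log2(CPM + 1) over each marker list in each gWAT library (points, shaped by replicate), with group mean and SD in black (n = 3). CPM here use library totals without scaling factors. For the lipid-associated macrophage list WT libraries lay at 6.70, 8.56 and 8.18 and KO libraries between 5.78 and 5.96.

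Single genes of inflammatory signals and matrix fell in KO gWAT. Of 17 cytokine and chemokine genes, Il1rn, which encodes the interleukin-1 receptor antagonist, fell from 82.4 to 11.8 CPM (−2.81 ± 0.42) and Ccl9, a chemokine, from 495 to 236 CPM (−1.07 ± 0.24), 2 genes over all genes tested and 5 adjusted over the list alone. The count of 5 was 8 without WT replicate 1, 1 without WT replicate 4 or KO replicate 3, 2 without KO replicate 1 and 3 without KO replicate 4. The list's median was −0.56 (adjusted p = 0.00135, and adjusted p = 0.48 with an estimated correlation, the highest of its alternatives). Of 24 matrix genes 1 fell over all genes tested, Timp1, an inhibitor of metalloproteinases (−1.72 ± 0.34), while adjusted over the list alone 7 fell and 1 rose. The 7 became 11 without WT replicate 1, 4 without WT replicate 4, 0 without KO replicate 1, where 0 rose, and 2 without KO replicate 3. Col1a1, a chain of type I collagen, was at 1046 CPM in WT and 512 CPM in KO but did not pass (−1.03 ± 0.25, adjusted p = 0.0518), nor did Thbs1, thrombospondin 1 (1.32 ± 0.32, adjusted p = 0.0513). The matrix list had a median of −0.37 (adjusted p = 0.000117, and adjusted p = 0.48 with an estimated correlation, the highest of its alternatives). The lipid-associated macrophage list had a median of −2.15 and the macrophage list −0.62 in the same libraries, and a change in the mix of cells was not separated from these falls.

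Genes of cholesterol synthesis fell as a group. Of 18 tested genes, 9 fell and 1 rose over all genes tested, and 14 fell and 1 rose adjusted over the list alone, with a median of −0.74. Lss, lanosterol synthase (ENSMUSG00000033105, chromosome 10, 76531588 to 76557138), fell from 89.5 ± 6.62 to 46.7 ± 2.14 CPM (−0.94 ± 0.10, adjusted p = 0.0154). Dhcr7, which makes cholesterol in the last step of a branch of the pathway (−1.04 ± 0.12), Sqle, squalene epoxidase (−0.83 ± 0.15), and Cyp51, lanosterol demethylase (−0.80 ± 0.13), also fell. The gene that rose was Fdft1, squalene synthase. The adjusted p was 4.86e-12, with adjusted p = 0.12 with an estimated correlation, the highest of its alternatives, and 0.0032 by fry, where it was the 1 list called. In the same KO libraries the lipid-associated macrophage list was lower by more, with a median of −2.15.

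Some adipocyte and mesothelial genes rose in KO gWAT. Of 15 genes of white adipocyte identity, 4 rose over all genes tested and 5 adjusted over the list alone (12 without WT replicate 1), with 0 lower in either. They were Cfd, given above, Agt, angiotensinogen, from 38.5 ± 8.73 to 126 ± 11 CPM (1.71 ± 0.17, adjusted p = 0.0154), Nnat, neuronatin, from 411 to 895 CPM (1.12 ± 0.23), and Retn, the adipokine resistin, from 368 to 919 CPM (1.32 ± 0.28). Adipoq, adiponectin, did not pass at 2212 CPM in WT and 3803 CPM in KO (0.78 ± 0.20, adjusted p = 0.0587). Of the 15 genes 14 had positive values and 1 a negative one. Lep, leptin, had a lower mean in KO, with overlapping groups, and did not pass. It was at 5171 CPM in WT and 3691 CPM in KO on library totals without scaling factors. The list's median was 0.37 (adjusted p = 5.36e-08, and adjusted p = 0.48 with an estimated correlation, the highest of its alternatives), with 0.24 without WT replicate 3 and 0.56 without WT replicate 1. A list made to detect brown fat around the heart also passed, with a median of 0.58 over 8 genes, of which 3 passed over all genes tested and 4 adjusted over the list alone (adjusted p = 6.75e-06, and adjusted p = 0.48 with an estimated correlation, the highest of its alternatives). Its called genes were Cfd, Retn and Adrb3, the beta-3 adrenergic receptor (141 to 343 CPM, 1.28 ± 0.22), and most of its members are shared with the white adipocyte list.

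All 11 mesothelial genes, markers of the layer that covers the fat depot, had positive fold changes, with a median of 1.12. Over all genes tested 3 rose, Krt19 from 16.6 to 40.3 CPM (1.28 ± 0.22), Krt8 (1.15 ± 0.24), both keratins, and Msln, mesothelin, from 34.3 to 71.2 CPM (1.05 ± 0.24), while 11 rose adjusted over the list alone. The adjusted p was 1.89e-09, with adjusted p = 0.36 with an estimated correlation, the highest of its alternatives. Endothelial genes did not pass, with a median of 0.07 over 14 genes and 0.34 ± 0.19 for Kdr, a VEGF receptor (adjusted p = 0.56 for the list), though without KO replicate 3 the list passed (0.0035). Of 14 fibroblast and adipose progenitor genes, 0 passed over all genes tested in edgeR (6 at an unadjusted p under 0.05) and 3 rose adjusted over the list alone. Without WT replicate 1, 5 rose and 2 fell adjusted over the list alone. The count was 0 with the replicate block or without WT replicate 4 or KO replicate 1, 3 or 4. Gsn, gelsolin (0.77 ± 0.19, adjusted p = 0.0544), and Dcn, decorin (0.56 ± 0.15, adjusted p = 0.0724), had the values nearest to the threshold among those named. The fibroblast list's median was 0.19 (adjusted p = 0.0407, and adjusted p = 0.48 with an estimated correlation, the highest of its alternatives), and its call was lost without WT replicate 1 (0.14), WT replicate 4 (0.064) or KO replicate 4 (0.15). That median ranged from 0.12 without KO replicate 4 to 0.30 without KO replicate 3, and was 0.29 without WT replicate 3.

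Single genes of amino acid catabolism and insulin signalling rose in KO gWAT. In the same libraries the white adipocyte list had a median of 0.37, the lipid-associated macrophage list −2.15 and the macrophage list −0.62, and no test here separated these values from a change in the mix of cells. Of 19 genes of ketone and branched-chain amino acid catabolism, Ivd, isovaleryl-CoA dehydrogenase, rose from 104 to 186 CPM (0.84 ± 0.18) and Ppm1k, the phosphatase that activates the branched-chain keto acid dehydrogenase, by 0.77 ± 0.15, while 8 rose adjusted over the list alone. That count was 18 without WT replicate 1, 0 without WT replicate 4 or KO replicate 1, 2 without WT replicate 3 or KO replicate 3 or 4, and 13 with the replicate block. The median was 0.45 (adjusted p = 9.48e-08, and adjusted p = 0.48 with an estimated correlation, the highest of its alternatives). The 10 tested transcripts of the mitochondrial genome had a median of 0.45, with 0 past the threshold in edgeR over all genes tested or adjusted over the list alone (4 at an unadjusted p under 0.05), and 0.68 ± 0.22 for mt-Nd5 (adjusted p = 0.00135 for the list, and adjusted p = 0.58 with an estimated correlation, the highest of its alternatives). Adjusted over the list alone 10 passed without WT replicate 1, where the median was 0.76, and 4 with the replicate block, and without WT replicate 3 the median was 0.28. Irs1, the insulin receptor substrate, rose from 27.3 to 52.7 CPM (0.95 ± 0.15), 1 of 16 insulin signalling genes over all genes tested and adjusted over the list alone. That list had a median of 0.32 (adjusted p = 0.00957, and adjusted p = 0.53 with an estimated correlation, the highest of its alternatives). Without WT replicate 1, 10 insulin signalling genes rose and 2 fell adjusted over the list alone, and the median was 0.52. Without KO replicate 1, 2 rose, and without WT replicate 3 the median was 0.17. Nuclear-encoded oxidative phosphorylation genes did not pass (median 0.11, adjusted p = 0.054, Ndufv1 0.27 ± 0.10), but did without WT replicate 1 (0.022), KO replicate 3 (0.017) or KO replicate 4 (0.034).

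Some genes of heat-producing fat fell in KO gWAT. Of 20 thermogenic and beige adipocyte genes 14 were tested. Of these, 3 fell and 1 rose over all genes tested, and 5 fell and 1 rose adjusted over the list alone, with a median of −0.42. Ucp1 of this list was nearly absent, at 0.17 CPM in WT and 0.086 CPM in KO on library totals without scaling factors. On the same scale Cidea was at 2.12 CPM in WT and 2.25 CPM in KO. Otop1, a proton channel, fell from 20.03 to 5.92 CPM (−1.76 ± 0.20, adjusted p = 0.0156) and Gk, glycerol kinase, from 24.5 to 12.2 CPM (adjusted p = 0.0221). Elovl3, a fatty acid elongase, fell by 3.06 ± 0.56 on 78 reads in WT and 9 in KO libraries. Ebf2, a transcription factor of brown and beige precursors, rose (0.67 ± 0.11). The adjusted p was 0.00265, with adjusted p = 0.36 with an estimated correlation, the highest of its alternatives, and the call was lost without WT replicate 1 (0.14). Of 8 genes of creatine and calcium cycling, Ryr2, a calcium release channel (−1.09 ± 0.22), and Slc6a8, the creatine transporter (−1.73 ± 0.38), fell over all genes tested and 4 fell adjusted over the list alone. That list's median was −0.59 (adjusted p = 0.0136, and adjusted p = 0.36 with an estimated correlation, the highest of its alternatives). In the same libraries the lipid-associated macrophage list had a median of −2.15, the macrophage list −0.62, the white adipocyte list 0.37 and the mesothelial list 1.12. Whether these falls reflect the mix of cells was not tested.

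Lipid storage and sugar use showed single genes that changed in lists that did not pass. Plin2, a lipid droplet coat protein, fell from 1324 to 476 CPM (−1.48 ± 0.22) and Adrb3 and Fabp5 changed as given above, while the list of lipid uptake and lipolysis did not pass (adjusted p = 0.84, with 3 higher and 2 lower of 16 adjusted over the list alone). Pkm, pyruvate kinase, fell by 0.55 ± 0.12 on the log2 scale within a glycolysis list that did not pass (adjusted p = 0.43, with 3 higher and 1 lower of 20 adjusted over the list alone). Acly, ATP citrate lyase, had a value of −0.48 ± 0.12 (adjusted p = 0.054) in a lipogenesis list that did not pass (adjusted p = 0.33, with 1 lower of 15 adjusted over the list alone), but did without WT replicate 3 (0.033). Hadha, of mitochondrial fatty acid oxidation, had −0.38 ± 0.10 (adjusted p = 0.0621) and its list did not pass (adjusted p = 0.93). These counts adjusted over the list alone moved with single libraries: the higher ones were 5 for lipid uptake without WT replicate 1 and 1 without WT replicate 3 or 4 or KO replicate 3 or 4. For glycolysis 3 rose and 3 fell without WT replicate 1, and 0 passed in edgeR without any other library (4 to 9 at an unadjusted p under 0.05). For lipogenesis 4 rose and 3 fell without WT replicate 1, 5 fell without WT replicate 3, and 0 passed in edgeR without any other library (4 or 5 at an unadjusted p under 0.05). With the replicate block 1 rose and 2 fell for lipid uptake, 1 rose for glycolysis, and 1 rose and 3 fell for lipogenesis.

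Interferon and ribosomal protein genes passed as lists with 0 genes past the threshold in edgeR, over all genes tested or adjusted over the list alone, and 4 and 1 at an unadjusted p under 0.05. The 22 interferon response genes had a median of 0.26, with 0.71 ± 0.22 for Ifit1 and 0.64 ± 0.19 for Gbp3 (adjusted p = 0.0416 for the list, and adjusted p = 0.87 with an estimated correlation, the highest of its alternatives). The 26 ribosomal protein genes had a median of −0.16, with −0.33 ± 0.13 for Rps16 (adjusted p = 0.0416 for the list, and adjusted p = 0.87 with an estimated correlation, the highest of its alternatives). Without KO replicate 1 the interferon median was −0.04, with 10 positive and 12 negative values, and it was 0.11 without WT replicate 1 and 0.40 without WT replicate 3. Adjusted over the list alone 2 interferon genes rose without KO replicate 4 and 1 ribosomal gene fell without WT replicate 1. The ribosomal median was −0.25 without WT replicate 1 and −0.10 without WT replicate 3. The interferon call was lost without WT replicate 1 (0.34), WT replicate 4 (0.061) or KO replicate 1 (0.61). The ribosomal call was lost without WT replicate 3 (0.20), WT replicate 4 (0.11), KO replicate 3 (0.11) or KO replicate 4 (0.074). Over the 48 lists tested in gWAT, camera called 17, 8 higher and 9 lower, with 0 called with an estimated correlation (6 at an unadjusted p under 0.05) and 1 by fry.

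**Figure D4:**
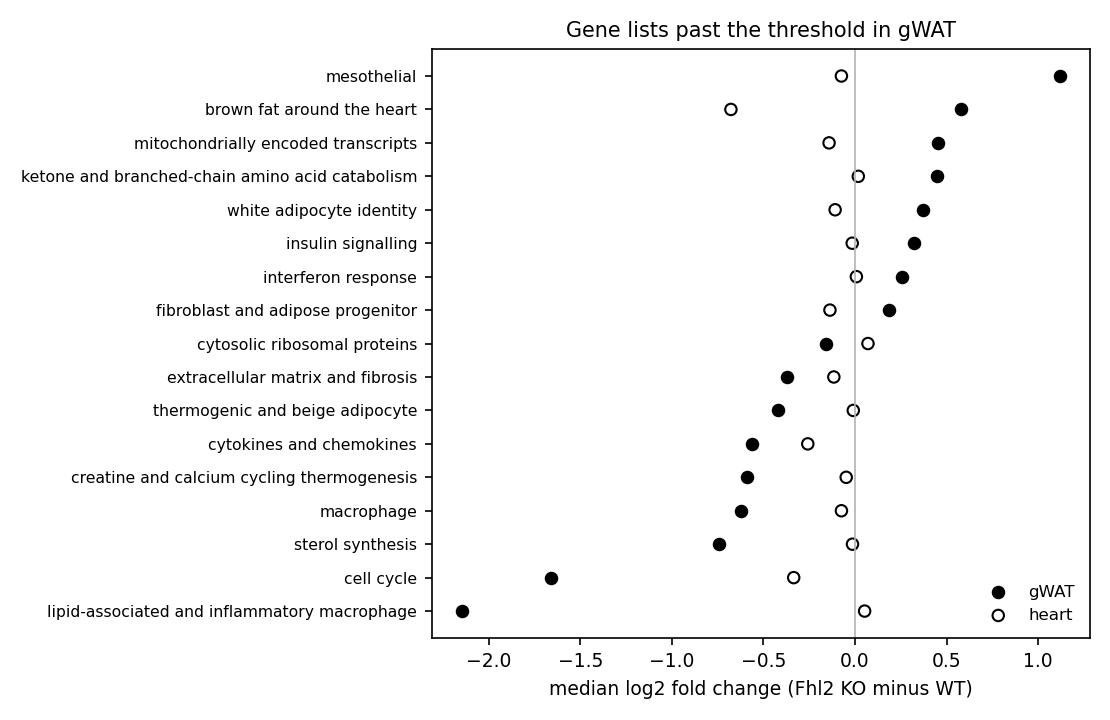
Median log2 fold change of KO over WT for each gene list past the threshold in gWAT (filled points), with the same list in heart (open points). The lipid-associated macrophage list lay at −2.15 and the cell cycle list at −1.66 in gWAT, and the mesothelial list at 1.12.

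Between KO and WT hearts edgeR called no gene beyond Fhl2, which does not show that the hearts were alike. Mthfd2 (ENSMUSG00000005667, chromosome 6, 83305691 to 83325908), a mitochondrial folate enzyme, had the next smallest p, at 6.64 ± 0.967 CPM in WT and 12.2 ± 1.89 CPM in KO (0.88 ± 0.14), but did not pass (adjusted p = 0.60, with 0.0043 to 1.0 over its alternatives). The other genes with the smallest p and positive values were Sec14l5 (1.01 ± 0.19), Ubxn10 (0.86 ± 0.19), Hacl1, an enzyme of fatty acid alpha-oxidation (1.32 ± 0.30), and Igfbp3, a binding protein of insulin-like growth factors (0.44 ± 0.10), none of which passed. Those with negative values were Lonrf2 (−0.65 ± 0.12), Ptpn12, a phosphatase (−0.33 ± 0.07), Sik1, a salt-inducible kinase (−0.41 ± 0.09), Slc25a25, a mitochondrial carrier (−0.46 ± 0.10), and Ppp1ccb (−0.95 ± 0.22), none of which passed. Ppp1ccb is annotated as a transcribed processed pseudogene, so its reads could belong to its parent gene. Of 14159 tested genes edgeR called 1, Fhl2, with 453 at an unadjusted p under 0.05. With a covariate for replicates 1 and 2 against 3 and 4, added after the data were seen, it called 2, with 804 at an unadjusted p under 0.05. With the replicate numbers as a block it called 1, with 759. DESeq2 called 2, adding Mthfd2, and gave 331 at an unadjusted p under 0.05. edgeR called 1 gene within replicates 1 and 2 alone and 17 within replicates 3 and 4 alone. In simulated counts with the same spread, 43.3% of 67 1.5-fold changes, 79.1% of 67 2-fold changes and 98.5% of 66 4-fold changes were called in heart. With 1 call, as in the real hearts, the adjustment asks for a smaller p, so these shares overstate what the fit could detect.

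Heart libraries of both genotypes fell into 2 sets by replicate number. Replicates 1 and 2 held many more transcripts of atrial cardiomyocytes than replicates 3 and 4: Myl7, the atrial myosin light chain, was at 611 and 650 CPM in WT replicates 1 and 2 and at 5.04 and 13.1 CPM in WT replicates 3 and 4. Myl4, another atrial myosin light chain, was at 870 and 778 CPM against 7.47 and 22.6 CPM. The first principal component, with 41.1% of the variance, separated the same sets, which were read from these data and are not labelled. All 8 atrial genes tested over the 8 hearts had positive fold changes in KO, with a median of 0.45. Within numbers 1 and 2 alone 9 were tested, 8 positive and 1 negative, with a median of 0.30, and within numbers 3 and 4 alone 8, 7 positive and 1 negative, with a median of 2.97. Bmp10, an atrial growth factor, had 2.03 ± 1.22 and Dkk3 0.80 ± 0.95, with 0 genes past the threshold in edgeR over all genes tested, adjusted over the list alone or at an unadjusted p under 0.05. With the replicate numbers as a block the median was 1.41 and 7 of 8 rose adjusted over the list alone, with 0 past the threshold over all genes tested. With the number sets as a covariate the median was 1.39 and 7 rose adjusted over the list alone, and within numbers 3 and 4 alone 5 rose over all genes tested and 7 adjusted over the list alone. When 1 library was left out the median ranged from 0.04 (KO replicate 2) to 0.96 (WT replicate 1, where 1 gene rose adjusted over the list alone). The atrial list passed by camera (adjusted p = 0.00811, with adjusted p = 0.96 with an estimated correlation and up to 1.0 over its alternatives). Its call was lost without WT replicate 3 (0.23), WT replicate 4 (0.13), KO replicate 1 (0.13) or KO replicate 2 (0.11).

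**Figure D5:**
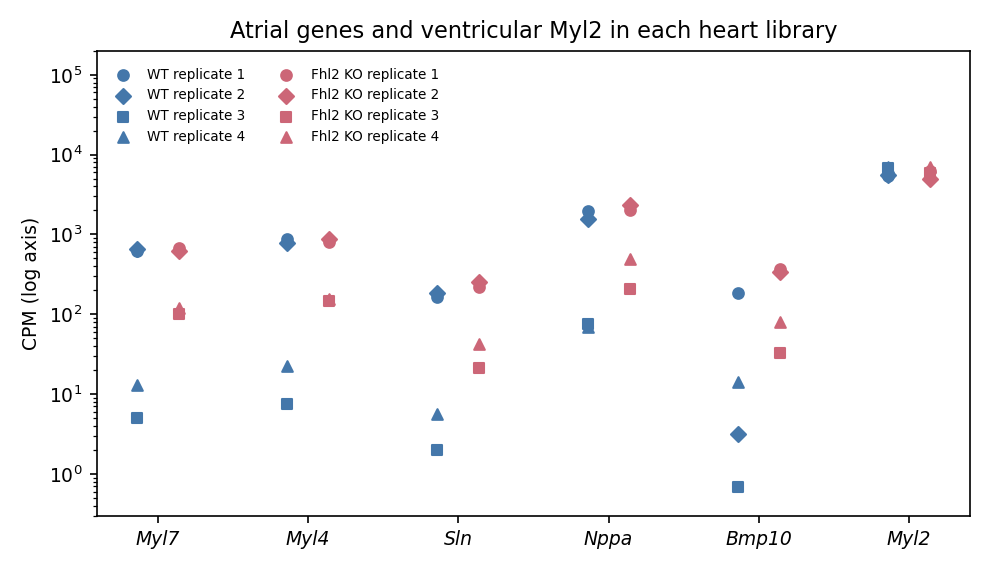
Level of atrial genes and of ventricular Myl2 in each heart library (points, shaped by replicate) in CPM on a log axis, with WT in blue and KO in red. Myl7 lay at 611 and 650 CPM in WT replicates 1 and 2 and at 5.04 and 13.1 CPM in WT replicates 3 and 4.

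Lists of cell cycle and heat shock genes passed in heart with negative medians and lists of erythroid and FOXO target genes with positive ones, by camera at the preset correlation alone. In edgeR 0 of their genes passed, over all genes tested or adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 1, 0 and 0 genes of these lists. Of 16 cell cycle genes 13 had negative values, with a median of −0.33 (0.08 within numbers 1 and 2, where 10 were positive, and −0.58 within 3 and 4), −0.63 ± 0.22 for Top2a and −0.61 ± 0.32 for Nusap1, a spindle protein (adjusted p = 0.000659). All 12 heat shock genes had negative values, with a median of −0.19 (−0.29 and −0.05 within the sets), −1.90 ± 0.78 for the inducible chaperone Hspa1b and −0.19 ± 0.09 for the constitutive Hspa8 (adjusted p = 0.00168). All 7 erythroid genes had positive values, with a median of 0.51 (−0.66 and 2.09 within the sets) and 0.66 ± 0.40 for Hbb-bt, a globin (adjusted p = 0.00316). That median was 0.05 without KO replicate 3, where 5 of 7 were positive, 0.18 without WT replicate 4, and 1.36 without WT replicate 2, where 7 rose adjusted over the list alone. Within numbers 1 and 2, 7 of 8 erythroid genes had negative values, and within 3 and 4, 7 rose adjusted over the list alone. With the replicate numbers as a block 1 erythroid gene rose and 2 heat shock genes fell adjusted over the list alone, with medians of 0.76 and −0.17. Within numbers 1 and 2 alone 5 heat shock genes fell adjusted over the list alone. Of 14 FOXO targets 13 had positive values, with a median of 0.13 (0.16 and 0.03 within the sets), 0.21 ± 0.10 for Bnip3, a mitophagy receptor, and 0.26 ± 0.15 for Txnip, a thioredoxin inhibitor (adjusted p = 0.00329). For each of these 4 lists adjusted p = 0.96 with an estimated correlation, and up to 1.0 over its alternatives. When 1 library was left out the cell cycle median ranged from −0.59 (WT replicate 2) to −0.17 (WT replicate 4), and the heat shock median was −0.11 without WT replicate 2. Calls were lost for cell cycle without KO replicate 4 (0.091), heat shock without WT replicate 2 (0.14), erythroid without WT replicate 4 (0.26) or KO replicate 3 (0.22), and FOXO targets without WT replicate 2 (0.087) or KO replicate 4 (0.090).

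Lists of matrix, fibroblast, actin and stress hormone genes passed in heart with small negative medians, by camera at the preset correlation alone. Of 24 matrix genes 19 had negative values, with a median of −0.12 (−0.21 within numbers 1 and 2, 0.02 within 3 and 4), −0.27 ± 0.11 for Loxl1, a collagen crosslinker, and −0.24 ± 0.10 for Tgfb1, a profibrotic cytokine (adjusted p = 0.0164). Of 14 fibroblast genes 11 had negative values, with a median of −0.14 (−0.20 and −0.02 within the sets), −0.34 ± 0.16 for Mfap5 and −0.20 ± 0.10 for Cd34 (adjusted p = 0.0219). Of 18 targets of serum response factor, which drives actin genes, 14 had negative values, with a median of −0.10 (−0.24 and 0.04 within the sets), −0.34 ± 0.10 for Cnn2 and −0.27 ± 0.09 for Tpm4 (adjusted p = 0.0164). Of 15 glucocorticoid-responsive genes 10 had negative values, with a median of −0.15 (−0.18 and −0.17 within the sets), −0.72 ± 0.24 for Lcn2, lipocalin 2, and −0.23 ± 0.09 for Sgk1, a kinase (adjusted p = 0.0143). In edgeR 0 genes of these lists passed over all genes tested or adjusted over the list alone, with 2, 0, 3 and 3 at an unadjusted p under 0.05. With the replicate numbers as a block, 3 glucocorticoid genes and 1 serum response factor target fell adjusted over the list alone, and 0 matrix or fibroblast genes did. Within the number sets, serum response factor targets passed in opposite directions adjusted over the list alone, with 5 lower within numbers 1 and 2 and 3 higher and 1 lower within 3 and 4, and 2 fell without WT replicate 4. In the same way 2 glucocorticoid genes and 1 fibroblast gene fell within numbers 1 and 2, and 1 glucocorticoid gene rose and 1 fell within 3 and 4, while 1 glucocorticoid gene fell without WT replicate 2. When 1 library was left out the medians ranged from −0.19 (KO replicate 3) to −0.05 (KO replicate 1) for matrix, −0.21 (WT replicate 4) to −0.02 (WT replicate 2) for fibroblasts, −0.17 (WT replicate 3) to 0.00 (WT replicate 1) for serum response factor targets, and −0.30 (KO replicate 1) to 0.01 (KO replicate 3) for glucocorticoid genes. For each list adjusted p = 0.96 with an estimated correlation, and up to 1.0 over its alternatives. The matrix call was lost without WT replicate 1 (0.34), KO replicate 1 (0.45) or KO replicate 4 (0.28), and the fibroblast call without WT replicate 1 (0.13), WT replicate 2 (0.45) or KO replicate 4 (0.37). The serum response factor call was lost without WT replicate 1 (0.89), WT replicate 2 (0.12) or KO replicate 4 (0.090), and the glucocorticoid call without WT replicate 1 (0.33) or KO replicate 3 (0.51).

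Lists of stress response and ribosomal genes passed in heart with small positive medians, and lists of mitochondrially encoded transcripts and macrophage genes with small negative ones, by camera at the preset correlation alone. Of 18 genes of the unfolded protein and integrated stress response 11 had positive values, with a median of 0.08 (0.08 within numbers 1 and 2, 0.09 within 3 and 4). Mthfd2, given above, is 1 of them and was the 1 gene higher adjusted over the list alone, and Atf5, a stress-induced transcription factor, had 0.32 ± 0.11 (adjusted p = 0.0169 for the list). Of 26 ribosomal protein genes 21 had positive values, with a median of 0.07 (0.11 and 0.03 within the sets) and 0.21 ± 0.08 for Rps6 (adjusted p = 0.0199). Of 13 mitochondrially encoded transcripts 11 had negative values, with a median of −0.14 (−0.08 and −0.19 within the sets), and −0.42 ± 0.22 for mt-Atp6 (adjusted p = 0.0236). The value of mt-Co2, −1.23 ± 0.57, rested on WT replicate 3, at 184 CPM against 24.5 to 34.5 CPM in the other WT hearts, and was −0.03 without it (heart mt-Co2 log2 fold change). Of 17 macrophage genes 13 had negative values, with a median of −0.07 (0.08 and −0.17 within the sets), −0.26 ± 0.10 for Adgre1 and −0.17 ± 0.09 for Mrc1 (adjusted p = 0.0486). For each of the 4 lists adjusted p = 0.96 with an estimated correlation, and up to 1.0 over its alternatives. Beside Mthfd2, 0 of their genes passed in edgeR adjusted over the list alone, and 0 passed over all genes tested, with 2, 1, 0 and 1 at an unadjusted p under 0.05. With the replicate numbers as a block 2 stress response genes rose adjusted over the list alone, and 0 genes of the other 3 lists passed. Within numbers 3 and 4 alone 5 mitochondrially encoded and 4 macrophage genes fell adjusted over the list alone. The stress response call was lost without WT replicate 3 (0.065), WT replicate 4 (0.34) or KO replicate 1 (0.13), and the ribosomal call without WT replicate 3 (0.13) or KO replicate 4 (0.090), while without KO replicate 1 its direction turned (median −0.01, adjusted p = 0.93). The other medians moved as well: for the stress response to 0.04 without KO replicate 1, for ribosomal genes to 0.12 without KO replicate 3, for macrophages to −0.18 without KO replicate 1, −0.04 without WT replicate 4 and 0.01 without KO replicate 4, and for mitochondrial transcripts to −0.22 without WT replicate 2, −0.09 without WT replicate 3 and −0.06 without WT replicate 4. The mitochondrial call was lost without WT replicates 3 (0.34) or 4 (0.34) or KO replicates 1 (0.40) or 2 (0.19), and the macrophage call without WT replicates 1 (0.11), 2 (0.14) or 4 (0.059) or KO replicates 3 (0.22) or 4 (0.91).

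Contractile and energy genes, which make up much of the heart's mRNA, did not pass as lists or as single genes over the 8 hearts, while some passed under alternatives. The 20 sarcomere genes had a median of −0.01 (0.05 within numbers 1 and 2, −0.04 within 3 and 4) and a positive mean, and camera ranked them as higher (adjusted p = 0.85, with 0.32 ± 0.14 for Myom2). The 24 calcium handling and ion channel genes had a median of 0.02 (0.06 and 0.00 within the sets, adjusted p = 0.57, with 0.33 ± 0.14 for Kcnj2, a potassium channel), and 1 rose adjusted over the list alone with the replicate block or without KO replicate 1. The cardiac stress and fetal program had a median of 0.06 (−0.13 within numbers 1 and 2, 0.35 within 3 and 4), with 0.46 ± 0.24 for Myh7, the slow myosin heavy chain, and −0.33 ± 0.19 for Rcan1, a calcineurin inhibitor (adjusted p = 0.32). Within numbers 3 and 4 alone heart Myh7 rose (heart Myh7 log2 fold change 1.11, adjusted p = 0.036), 1 of 2 genes of the list that rose over all genes tested, against 6 adjusted over the list alone. Within numbers 1 and 2 alone 2 fell adjusted over the list alone, and with the replicate block 2 rose. The list passed with the replicate numbers as a block (adjusted p = 0.020), without WT replicate 1 (0.044) and without WT replicate 2 (0.011). The fatty acid oxidation list had a median of −0.01 (0.06 and −0.06 within the sets) while camera ranked it as higher (adjusted p = 0.98, Cpt1a 0.07 ± 0.07). Nuclear-encoded oxidative phosphorylation had a median of −0.01 (adjusted p = 0.78, Ndufb10 −0.10 ± 0.09) but passed without WT replicate 1 (0.044). Its values lay on opposite sides in the number sets: 35 of 36 were positive within numbers 1 and 2, with a median of 0.11, and 36 of 36 negative within 3 and 4, with a median of −0.12. Glycolysis had a median of −0.04 (0.01 and −0.11 within the sets, adjusted p = 0.16, Eno3 −0.18 ± 0.09) but passed without WT replicate 2 (0.0082). Over the 49 lists tested in heart, camera called 13, 5 higher and 8 lower, with 0 called with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by fry.

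The effect of genotype differed between gWAT and heart for some genes, by a test of the difference itself in all 14 libraries. Mthfd2 fell in gWAT, from 18.5 ± 1.55 to 8.76 ± 0.347 CPM (−1.08 ± 0.13), where in heart its value was 0.88 ± 0.14, a difference of −1.96 (adjusted p = 0.000651). Ces1d, a carboxylesterase of lipid metabolism, rose in gWAT from 378 to 1092 CPM and differed from heart by 1.55 (adjusted p = 0.00611). The difference was also positive for Dock11 (1.09), St3gal6, a sialyltransferase (0.89), and Sqor, which oxidises sulphide (0.76). It was negative for Pcp4l1 (−3.61), Nceh1, a cholesterol ester hydrolase of macrophages (−2.11), Chchd10 (−1.25), the lysosomal protease Ctsl (−1.21) and Pdxk, pyridoxal kinase (−0.89). Their changes in gWAT were 0.84 ± 0.12 (Dock11), 0.88 ± 0.12 (St3gal6), 0.79 ± 0.10 (Sqor), −1.99 ± 0.32 (Nceh1), −1.26 ± 0.14 (Chchd10), −1.11 ± 0.18 (Ctsl) and −0.90 ± 0.10 (Pdxk). edgeR called 184 of 16014 genes for the difference, 58 with a more positive effect in gWAT and 126 with a more negative one. The count moved with every library left out: 31, 34, 57 and 60 without heart WT replicates 1 to 4, 59, 62, 46 and 62 without heart KO replicates 1 to 4, 1315, 13 and 3 without gWAT WT replicates 1, 3 and 4, and 18, 16 and 6 without gWAT KO replicates 1, 3 and 4. DESeq2 called 669, limma-voom 69, edgeR without a filter 533 and edgeR with the replicate numbers as a block across tissues 37. Of 21 named genes called for the difference, 9 passed with that block: Mthfd2, Ces1d, Dock11, Nceh1, Chchd10 and Pdxk, with Agt, Irs1 and Plin2. St3gal6 (adjusted p = 0.051), Sqor (0.051), Ctsl (0.085) and Pcp4l1 (0.085) were among the 12 that did not. In limma-voom 14 of the 21 passed, 13 to 18 without 1 heart library, 21 without gWAT WT replicate 1, and 3 to 11 without another gWAT library.

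Fhl2, the gene removed, was the 1 gene called in both tissues. Among 13370 genes tested in both, 690 were called in gWAT and 1 in heart, so sharing beyond Fhl2 was not tested. DESeq2 gave 2 shared genes, adding Mthfd2, which fell in gWAT and rose in heart. With atrial level as a covariate in heart, a fit chosen after seeing the data, 4 of 7 heart calls were called in gWAT too, all lower in both: Fhl2, Ccl9, Hmox1 and Sh3pxd2b, which were singled out after their values were seen. Of the 689 other gWAT calls, 422 (61.2%) had the same direction in heart and 31 had an unadjusted p under 0.05 there. Fold changes in the tissues were weakly related across genes, which are not independent replicates (Pearson r 0.058).

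Genes close to Fhl2 on chromosome 1 were compared with all others, since DNA of another strain can remain around a targeted gene. In gWAT 7 of 190 tested genes starting within 20 Mb were called (3.68%), against 826 of 14996 elsewhere (5.51%), an odds ratio of 0.656 that did not pass (Fisher's exact test, two-sided, p = 0.336). At an adjusted p under 0.1 the odds ratio was 1.03. Creg2, named above among the largest falls, is 1 of the 7, and the ratio does not settle the cause for a single neighbour. In heart edgeR called 0 of 165 such genes, and Fhl2 was the 1 call among all genes, so no ratio could be had.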

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

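The tests of the 3 patterns weighed here were all chosen after the results were seen, while the counts of other splits of the libraries were planned.

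Of 112 groups of 4 heart libraries tested for a library far from the others, 6 had one, where chance gives about 1 in 20. The gap to the nearest library, as a share of the whole range, was 0.995 for the mean log2 level of cell cycle genes in WT (replicate 2 at 1.44, others 1.77). It was 0.841 for Hacl1 (WT replicate 4 at 0.848 CPM, others 0.459 to 0.521) and 0.844 for Hbb-bt (WT replicate 2 at 155 CPM, others 43.8 to 61.3). It was 0.927 for Bmp10 (WT replicate 1 at 183 CPM, others 0.695 to 14.1) and 0.937 for mt-Co2 (WT replicate 3 at 184 CPM, others 24.5 to 34.5). In KO hearts it was 0.907 for Bnip3 (replicate 4 at 128 CPM, others 96.2 to 99.1). Groups of 3 in gWAT were not tested in this way.

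The genotype effect differed between the tissues for 184 genes by the interaction test, 21 of them named in the text. The effect in gWAT less that in heart was −1.96 for Mthfd2, 1.55 for Ces1d, 0.89 for St3gal6, −0.89 for Pdxk, −1.25 for Chchd10, −2.11 for Nceh1, −1.21 for Ctsl, 0.76 for Sqor, 1.09 for Dock11 and −3.61 for Pcp4l1. Among genes of the gWAT lists described above it was −3.57 for Gpnmb, −2.53 for Trem2, −0.88 for Lss, 1.53 for Agt, −1.07 for Gk, −1.67 for Slc6a8, −1.47 for Plin2 and 1.09 for Irs1. For Fam13a it was 2.04, for Fat3 −4.37 and for Lonrf2 1.34. Adjusted p of these 21 ranged from 0.000651 (Mthfd2) to 0.0412 (Trem2).

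Other splits of the libraries gave results as large in heart. As many genes as with the genotype split, 1, came from 5 of 35 splits, the genotype split included, so chance was not excluded by the count. The highest other count, 1057, came from the split of replicates 1 and 2 against 3 and 4, which points to a structure of the samples, and 30 splits gave 0 genes. Pairing of the heart samples by number was not shown beyond the sets of numbers. The 8 splits that part every 2 samples of equal number gave at most 0 genes beside the real 1. As many heart lists as the real 13 came from 23 of 35 splits, with 29 at the highest other, so chance was not excluded. Of the 8 splits that part equal numbers, 4 gave as many, with 19 at the highest other. The number-set split gave 29 lists. With the replicate numbers as a block edgeR called 1 heart gene and camera 17 lists. In gWAT there are 10 splits, too few for a share under 0.05. The genotype split gave 834 genes against 0 at the highest other, a count of 1 split. It gave 17 lists against 25 at the highest other, with 3 splits as large, the genotype split included. For the difference between tissues, 5 of 40 drawn regroupings gave at least the real 184 genes, the real grouping included, with 415 at the highest other. By the planned rule this share of 5 in 40 did not exclude chance. The other 4 kept the real gWAT groups and regrouped the hearts (276 to 415 genes), so they carry the gWAT effect. Of the 35 draws that mixed the gWAT groups, 0 reached 184, with 87 at the highest. With 10 gWAT splits in all, these draws reuse the same few gWAT groupings, so they cannot exclude chance either.

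A pattern that divides the heart libraries is the level of atrial genes, a candidate explanation of which is the share of atrial tissue in the dissected piece. By the means of the sets all 8 tested atrial genes were higher in replicates 1 and 2 than in 3 and 4 in both genotypes. Library by library this held for 8 in KO and 6 in WT, where Bmp10 was at 183 and 3.14 CPM in replicates 1 and 2 against 0.695 and 14.1 CPM in 3 and 4, and Nr2f1 overlapped as well. The atrial median shift exceeded the ventricular one by 5.17 in WT and 2.77 in KO, more than random deals of the members of both lists gave (shares 0.0017 and 0.0016). Such deals treat genes that move together as independent and do not measure the spread between samples. The number sets were read from these same genes, and mesothelial genes shifted with them (median 2.45 in WT and 1.40 in KO), Nppa, the most abundant of the atrial genes, being at 1976 and 1541 CPM in WT replicates 1 and 2 against 74.8 and 68.6 CPM. Library size or scaling is argued against by the sarcomere genes, whose median shift was −0.16 in WT and −0.06 in KO. Genotype stays open as a part of it, since the atrial median was higher in KO by 0.31 within replicates 1 and 2 and by 3.21 within 3 and 4 (differences of mean log2 CPM over the 8 genes, where edgeR fits within each set gave 0.30 over 9 genes and 2.97 over 8), which a different share of atrial tissue would give as well, so these cannot be told apart with 2 samples each.

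In gWAT the lower genes of lipid-associated macrophages were weighed against changes in the mix of cells. Cell cycle genes, with a median of −1.66, entered none of these tests, so the source of their fall stays open. A loss of macrophages of every kind alike is argued against by the lipid-associated list, whose median lay −1.53 from that of the macrophage list. Without 1 library the macrophage median ranged from −0.83 to −0.44. Of 10000 random deals of the members a share of 0.0004 gave as much, but deals treat genes as independent and do not measure the spread between samples. The macrophage list also holds genes of other cells, such as Lyve1, which can make its median smaller and limits this argument. A single library is argued against, since the weakest median of the lipid-associated list without 1 library was −1.74. Dilution by RNA of other cells is argued against by the endothelial genes, with a median of 0.0714 (SD 0.133 over members), and by the fibroblast median of 0.19. When 1 library was left out the endothelial median ranged from −0.04 (KO replicate 1) to 0.28 (KO replicate 3), with 0.16 without WT replicate 3, and the lipid-associated one from −2.55 to −1.74. An effect of genotype on these cells or their number, a difference between the mice in obesity and a difference in the dissected part of the depot were not tested and stay open, and Fabp5 of the list is also a gene of lipid uptake.

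The higher mesothelial genes in KO gWAT were weighed in the same way. For these genes, a loss of macrophage RNA that raised all other cells alike is argued against by their median, which exceeded the endothelial one by 1.05. A share of 0.0007 of random deals gave as much, which again does not measure the spread between samples. The white adipocyte list, with a median of 0.37, entered none of these tests, so this explanation stays open for the adipocyte genes. When 1 library was left out the mesothelial median was 0.89 (WT replicate 3) or more, and the endothelial one 0.28 or less. A larger share of depot surface in the dissected pieces is a candidate source of the mesothelial part: all 11 genes were higher, from 0.35 to 1.41, with an SD of 0.28, as a change in the share of 1 cell type would give. The most abundant mesothelial genes that were named, Krt19 and Msln, reached 40.3 and 71.2 CPM in KO, and all 11 are expressed in WT gWAT too. An effect of genotype stays open as untested, for the adipocyte genes as well, which the share of surface would not raise.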

How the results depend on the processing

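The fits within sets of heart replicate numbers, the covariates for these sets and for atrial level, library totals without scaling factors, and RLE scaling for lists were chosen after seeing the data, and the other alternatives were planned. The cause of a change was not tested except where fewer libraries or another threshold made it. Fhl2 kept its direction in both tissues under every alternative, and in heart its call. In gWAT named genes gave 179 unchanged, 346 weaker, 9 stronger and 0 reversed results when 1 library was left out, and 665 unchanged, 107 weaker and 27 stronger under the other settings. They were named by their values in these same libraries, so the 0 reversed results are not independent support. Of the 76 named genes called in gWAT, 59 passed in limma-voom, 73 with library totals, 34 without WT replicate 3, 76 without WT replicate 1 and 76 in DESeq2, while 64 of 75 passed in 1 fit of all libraries. In edgeR 0 of the 76 passed with the replicate block or without WT replicate 4 or KO replicate 1, 3 or 4, though 2922, 2374, 3191, 2736 and 2787 genes had an unadjusted p under 0.05. Heart genes gave 352 unchanged when 1 library was left out and 562 unchanged, 5 stronger and 2 reversed under the others. Interaction genes gave 180 unchanged and 114 weaker when 1 library was left out and 86 unchanged and 19 weaker under the others. Library totals moved the median fold change of all genes by less than 0.1 on the log2 scale in each tissue. The fold changes of Hmga2 and Nptx1 rest on 7 and 12 reads in KO gWAT, which limits their precision.

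The gWAT count of 834 genes (305 higher, 529 lower) was 1600 with no filter (585, 1015), 1769 in DESeq2 (671, 1098), 477 in limma-voom (213, 264), 1725 in 1 fit of all 14 libraries (583, 1142), and 1800 at an adjusted p under 0.1 (730, 1070). It was 0 (0, 0) at 0.01, with 3510 genes at an unadjusted p under 0.05, and 0 (0, 0) in edgeR with the replicate block, where 2922 genes had an unadjusted p under 0.05. Without 1 library it ranged from 0 to 2908 (0 to 1201 higher, 0 to 1707 lower). The heart count of 1 (0 higher, 1 lower) was 3 with no filter (2, 1), adding Gm37435 and Mthfd2, 2 in DESeq2 (1, 1) and 2 with the number sets as a covariate (1, 1), both adding Mthfd2. It was 7 with atrial level as a covariate (0, 7), and 17 within numbers 3 and 4 (16, 1). The count for the difference between tissues, 184, was 533 with no filter, 669 in DESeq2, 69 in limma-voom, 37 with the block across tissues, and 3 to 1315 without 1 library. The shared count of 1 was 2 in DESeq2 and 0 with the block in both edgeR fits, which gave 2922 gWAT genes at an unadjusted p under 0.05. The odds ratio near Fhl2 turned from 0.656 to 1.03 at an adjusted p under 0.1.

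Called lists fell from 13 in heart and 17 in gWAT to 0 and 0 with an estimated correlation, and to 0 and 1 by fry. The replicate block changed the call of cardiac stress in heart (adjusted p = 0.020, and 0.045 with the number-set covariate) and of ribosomal proteins in gWAT (adjusted p = 0.074) and of no other described list. Myh7 turned to −0.20 within numbers 1 and 2, and Rcan1 to 0.19 within numbers 3 and 4 (heart Myh7 log2 fold change, heart Rcan1 log2 fold change). Fatty acid oxidation in heart turned with the block (adjusted p = 0.97), the number-set covariate (0.95) and fry (1.0), in gWAT with the block (0.99), and heart oxidative phosphorylation with library totals (0.85). When 1 library was left out some lists turned in some of the fits, at an adjusted p of 0.091 or more. Over all fits without 1 library, turned or not, adjusted p ranged from 0.044 to 0.81 for heart oxidative phosphorylation. It ranged from 0.091 to 0.79 for fatty acid oxidation, 0.25 to 0.84 for sarcomere and 0.11 to 0.91 for LIM-domain genes. For calcium handling it was 0.087 to 0.95, for cardiac stress 0.011 to 0.82, for ribosomal proteins 3.18e-05 to 0.93 and for the clock 0.49 to 0.96. In gWAT it ranged from 0.033 to 0.73 for lipogenesis, 0.23 to 0.94 for fatty acid oxidation, 0.39 to 0.90 for lipid uptake and 0.0035 to 0.93 for endothelial genes.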

Other observations

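All tests in this part were planned. Hypoxia and antioxidant genes of KO gWAT changed in both directions. Hmox1, haem oxygenase 1, fell from 124 ± 4.49 to 54.1 ± 4.57 CPM (SD, n = 3; log2 fold change −1.20 ± 0.10, adjusted p = 0.0101), and Srxn1, sulfiredoxin, by 0.68 ± 0.13 on the log2 scale. Gsta3, a glutathione transferase of a family of similar genes (1.39 ± 0.23), Gpx3, the secreted glutathione peroxidase (221 to 414 CPM, 0.91 ± 0.19), and Gsta4 rose, so that of 16 genes 3 rose and 2 fell over all genes tested, 3 rose and 5 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.48). The 5 became 2 without WT replicate 4 or KO replicate 1 or 4 and 3 with the replicate block, and the 3 became 5 without WT replicate 1. Vegfa, the endothelial growth factor, rose from 113 to 213 CPM (0.92 ± 0.17) and Ndrg1 by 0.65 ± 0.11, while Plin2 fell, and the hypoxia list of 12 genes did not pass (adjusted p = 0.27). Adjusted over the list alone 3 rose and 1 fell, or 7 and 4 without WT replicate 1.

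Clock, LIM-domain and stress response genes of KO gWAT also changed singly in lists that did not pass. Nr1d1, the repressor Rev-erb alpha, rose (103 to 172 CPM, 0.74 ± 0.16) and Nfil3, a repressor of clock output, fell (−0.73 ± 0.16), with 3 higher and 1 lower adjusted over the list alone. These counts were 5 and 2 without WT replicate 1, 0 and 0 in edgeR without WT replicate 4 (4 at an unadjusted p under 0.05), and 2 and 2 without KO replicate 3. The clock list had a median of 0.20 (adjusted p = 0.096) and passed without KO replicate 4, where the median was 0.32 (adjusted p = 0.0037). Of 23 LIM-domain genes other than Fhl2, Pdlim3 rose (1.31 ± 0.28) and Fhl3, the close relative of Fhl2, fell from 13.8 to 3.94 CPM (−1.81 ± 0.35), and the list did not pass (adjusted p = 0.13). Adjusted over the list alone 2 rose and 1 fell, against 7 and 4 without WT replicate 1, 4 and 2 without KO replicate 4, 1 and 1 without WT replicate 3 or 4, 0 and 0 in edgeR without KO replicate 1 or 3 (7 and 6 at an unadjusted p under 0.05), and 0 and 1 with the replicate block. Of 18 stress response genes Asns, asparagine synthetase, rose (0.68 ± 0.12) and Mthfd2 fell, and the list did not pass (adjusted p = 0.21). Adjusted over the list alone 1 rose and 3 fell, against 2 and 6 without WT replicate 1, 2 and 3 with the replicate block, and 1 and 1 without WT replicate 3 or 4 or KO replicate 1 or 4. In heart Npas2 and Arntl, partners in the clock, had 0.86 ± 0.28 and −0.58 ± 0.24 and Lmcd1, a LIM-domain protein, had −0.26 ± 0.10, none of which passed, nor did their lists (adjusted p = 0.85 and 0.53).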
